A study of Nicotiana attenuata with 24 samples.

How the data were processed

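Leaf RNA of *Nicotiana attenuata* (coyote tobacco, Utah accession) was measured on 24 one-colour Agilent arrays, 3 in each of 8 groups. Per the labels, the groups crossed 2 plant lines, an empty-vector line (EV) and a line (irCCaMK) in which CCaMK, a kinase controlled by calcium and calmodulin, was silenced, with inoculum holding or lacking living arbuscular mycorrhizal fungus (AMF), and with a harvest at 2 or 6 weeks post inoculation (wpi). The earlier harvest was at the rosette stage and the later at the elongation stage. Per the labels' protocols, EV and irCCaMK plants were grown together in pots under low phosphate, the fungal inoculum was a commercial *Rhizophagus irregularis* preparation, and the dead inoculum had been autoclaved. The labels number the arrays of each group 1 to 3 without saying whether these came from separate plants or pots, so p-values measure only the spread between these arrays, which may be technical.

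Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.3.1. Their intensity values used here are the processed signal, which the software had corrected for background and for spatial trend, and the median spot and local background signals, none of them normalized between arrays. Other deposited columns hold flags for spots well above background, saturated spots and outliers. The authors' value table is on a log2 scale: its column medians lay between 6.48 and 6.51, its maximum was 18.75 in every column, and the ranks in each column followed the median signal of the same array. The normalization behind that table, its centring and its treatment of background are not given in the sources used here. The table was used as an alternative only.

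The array carried 57157 probes. Probes are named by gene-model identifiers with no gene names or descriptions, and 0 of the probes matched the 39977 genes of the reference table, built on another annotation. The kinase targeted by silencing could therefore not be read from a named probe, and the 25 gene lists fixed before the data were examined matched no probe. These are not analysed here. By the rule fixed in advance for that case, each comparison names by identifier the 2 probes with the largest rise and the 2 with the largest fall among those past the threshold, or those with the smallest p where fewer than 4 passed. A gene model with several probes is represented by the one that ranked first in this way. The brightest probe, fixed in advance for this, was not used, so the choice followed the effect.

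Control spots were left out, spots flagged as outliers were set aside, and spots of one probe were averaged. The log2 processed signal was scaled by subtracting each array's 75th percentile. Of the probes, 23868 were not well above background on all 3 arrays of any group and 9 more lacked a value after outlier flags, which left 33280 for testing. No probe was saturated. Levels below are scaled log2 signals. Where a probe was not well above background on any array of one side, its fold is given as "at least", from the mean of the bright side against the higher of the dim probe's own signal and the lowest signal well above background on each array. Unlike the fitted differences, these folds and the group means are not adjusted for slide, which overlaps with AMF. All 24 arrays entered 1 limma fit (lmFit and eBayes, limma 3.58.1, R 4.3.3) with a term for the 8 groups and a fixed term for slide, with 14 residual degrees of freedom and a prior of 2.46. Calls are probes with a Benjamini-Hochberg adjusted p below 0.05, with no fold minimum. The 13 contrasts were AMF against control in each line and stage, irCCaMK against EV in each of 4 conditions and on average, the genotype by AMF interaction at each stage, the AMF by stage interaction in EV, and stage. The interaction is the AMF effect in EV minus that in irCCaMK.

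The arrays lay on 3 slides of 8, and each slide was 1 scan. Slide 1 held control arrays only, slide 3 AMF arrays only, and slide 2 held 1 array of every group. Contrasts of genotype, interaction and stage are balanced over slides. Contrasts of AMF against control within a line rest on slide 2 and on slide differences estimated within groups, so they have larger errors: the median standard error was 0.24, against 0.19 for a genotype contrast in 1 condition. The 75th percentile of the processed signal ranged from 212.5 to 1106 between arrays, and 50.0% to 60.3% of probes were well above background. The number of arrays limits the precision.

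The labels give the replicate numbers no meaning, so pairing was judged from the data, by the correlation of same-numbered arrays' deviations from their group means. In 2 of 8 comparisons of 2 groups every pair lay over the bound of 0.1: controls of the 2 lines at 6 wpi (0.658, 0.298 and 0.409), and control and AMF arrays of irCCaMK plants at 6 wpi (0.38, 0.361 and 0.154). The bound was applied to each comparison after the blocked counts had been seen. Blocked counts stand beside these 2 results.

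The fit was tested on simulated data with 33280 probes. For AMF against control in EV at 2 wpi it recovered 42.0% of probes changed 2-fold and 84.0% of those changed 4-fold. For irCCaMK against EV with AMF at 6 wpi the shares were 62.0% and 92.0%, and for the interaction at 6 wpi 34.0% and 72.0%. The simulated spread was independent between probes.

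Alternatives fixed before the data were examined were: no slide term, slide as a random block, slide with array column, normexp background correction, quantile or median normalization, no filter or a stricter filter on dim probes, the authors' table, eBayes with trend and robust, only the compared groups, a 2-fold minimum, the replicate number as a block, values within slides, and each array left out. The scanner files used here give a median and no mean spot signal, so normexp ran on the median signal and median local background. Alternatives added after the data were examined were the array labelled EV control 2 wpi replicate 3 left out together with the slide term, array brightness as a covariate, and slides 1 and 3 alone. Tables and figures were made with Python, pandas and matplotlib.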

Results

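The data describe the leaf transcriptome of an empty-vector line and of a line silenced for a kinase of the common symbiosis pathway (CCaMK, which decodes calcium signals during root colonisation by mycorrhizal fungi), with or without living AMF inoculum, at 2 and 6 wpi. Each of the 8 groups had 3 arrays. Arrays of one group correlated with r between 0.9612 and 0.9901 across the 33280 tested probes. The first principal component held 66.7% of the variance and separated the stages, and the second held 7.3% and set irCCaMK plants with AMF at 6 wpi apart. These 3 arrays were also brighter before scaling, with a 75th percentile of 1047 ± 55.1 (SD, n = 3) against 644.7 ± 34.4 (SD, n = 3) in EV plants with AMF at 6 wpi, and 59.3% against 55.8% of their probes were well above background.

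**Figure D1:**
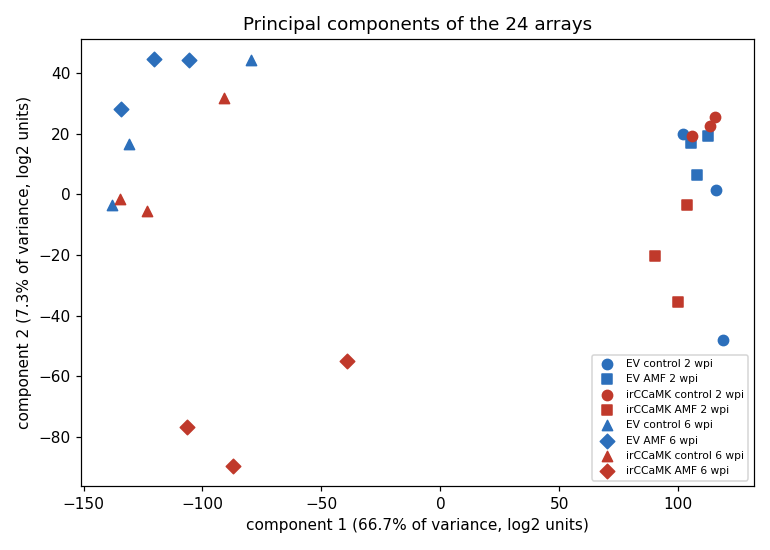
Principal components of the 24 arrays, in log2 units, with EV in blue and irCCaMK in red and 1 symbol per treatment and stage. Component 1 (66.7% of variance) separates 2 from 6 wpi, and the 3 irCCaMK arrays with AMF at 6 wpi lie lowest on component 2 (7.3%).

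The array labelled EV control 2 wpi replicate 3 goes against its label at a probe that separated the lines. NIATv7_g03207.t1.cds1 measured 8.28 and 8.34 on the other 2 arrays of its group, 8.51 on average in EV plants with AMF at 2 wpi, and -0.12 on average in irCCaMK plants at 2 wpi, and the array in question read 0.14. It was kept under its label, and counts without it are given where they differ by more than 1.5 times.

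The largest difference between lines was found with AMF at 6 wpi. NIATv7_g05642.t1.cds1 measured 2.76 ± 1.04 (SD, n = 3) in irCCaMK plants and was not well above background in EV plants (measured mean -7.51), at least 248-fold lower. NIATv7_g40584.t1.cds1 measured 5.45 ± 0.98 in irCCaMK and -4.22 ± 0.54 in EV plants, a log2 difference of 9.67 ± 0.63 (SE). Both probes were high in every group at 2 wpi, where NIATv7_g40584.t1.cds1 lay between 5.27 and 6.36, and in controls at 6 wpi it measured -2.16 ± 1.25 in EV and -2.83 ± 1.34 in irCCaMK plants. NIATv7_g03207.t1.cds1 fell by 6.63 in irCCaMK plants, and NIATv7_g29359.t2.cds2, not well above background there, was at least 13.5-fold lower than in EV; other probes of the latter gene model measured log2 differences of 0.51 and -0.35. limma called 7220 probes, 3389 higher and 3831 lower in irCCaMK, of which 2760 differed at least 2-fold, 1684 higher and 1076 lower. They stand for 5032 gene models, and in 1548 of the 1688 models with several probes all probes had the same sign. Under normexp correction 2693 of 8309 calls were higher and 5616 lower. The count was 4228 without EV AMF 6 wpi replicate 1, 4069 with only these 2 groups in the fit, 3588 with array brightness as a covariate and 2359 from slide 3 alone.

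**Figure D2:**
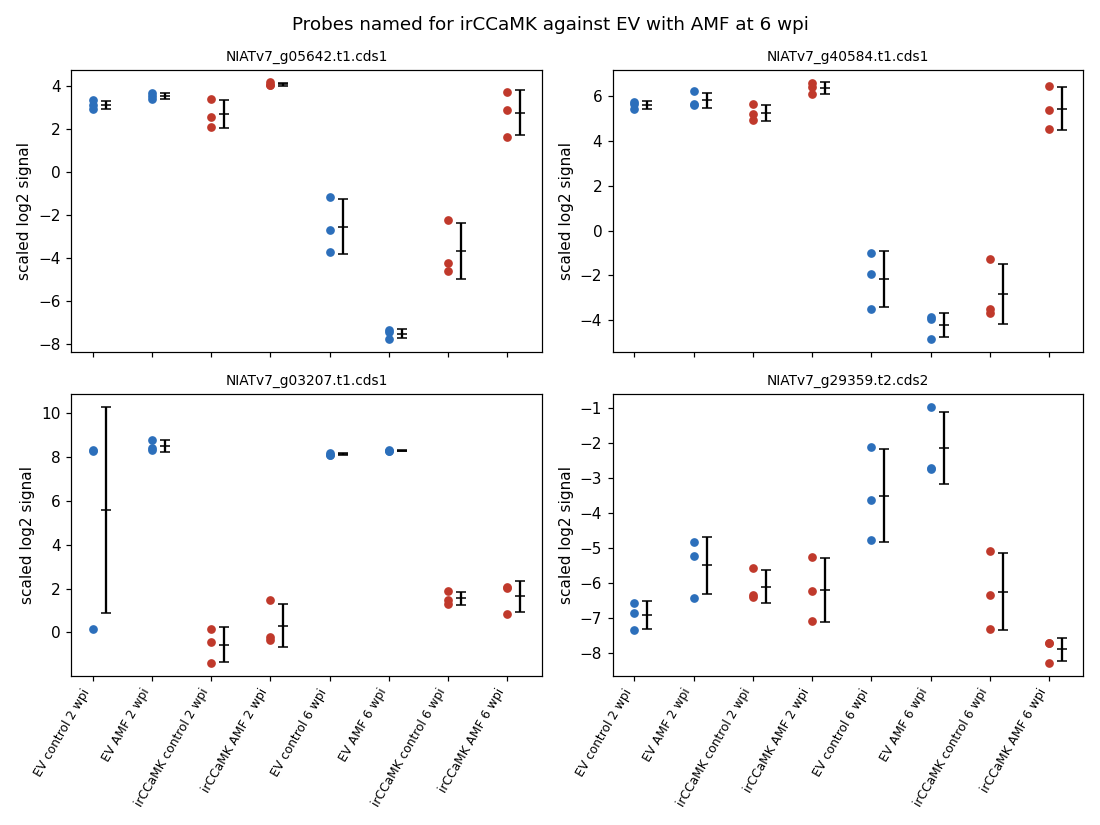
Scaled log2 signal of the 4 probes named for irCCaMK against EV with AMF at 6 wpi, with 1 point per array (EV blue, irCCaMK red) and the group mean ± SD in black. NIATv7_g05642.t1.cds1 and NIATv7_g40584.t1.cds1 are high in irCCaMK plants with AMF at 6 wpi, at means of 2.76 and 5.45, and the array labelled EV control 2 wpi replicate 3 reads 0.14 at NIATv7_g03207.t1.cds1.

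In the other 3 conditions far fewer probes were called between the lines. With AMF at 2 wpi, NIATv7_g03207.t1.cds1 measured 0.31 ± 1.00 in irCCaMK and 8.51 ± 0.26 in EV plants (SD, n = 3), and NIATv7_g34157.t1.cds1 was not well above background in irCCaMK plants, at least 39.8-fold lower than in EV. NIATv7_g08194.t1.cds1 was higher in irCCaMK plants, at 1.86 ± 0.52 against -0.62 ± 0.22, and NIATv1_g51512.t1.cds1 was at least 1.96-fold higher. The limma fit called 70 probes there, 36 higher and 34 lower. Scaling changed the balance: quantile normalization gave 74 higher and 42 lower, the authors' values gave 113 and 61, and normexp 14 and 21. In controls at 6 wpi, 18 probes were called, 4 higher and 14 lower (2 and 18 with quantile normalization): NIATv7_g15582.t1.cds1 rose by 2.56 ± 0.38 (SE) on the log2 scale, XLOC_027546.t1.cds1 was at least 2.92-fold higher, and NIATv1_g52274.t1.cds1 and NIATv1_g52349.t1.cds2 were at least 2.37-fold and 2.36-fold lower. With same-numbered arrays as pairs in a block 6 probes were called there, of which 2 were among the 18. In controls at 2 wpi, 8 probes were called, all higher in irCCaMK (2 higher and 2 lower with quantile normalization), with NIATv7_g49367.t1.cds1 at least 2.51-fold and NIATv7_g32087.t1.cds1, well above background on 1 of 3 irCCaMK arrays, at least 1.46-fold higher. Without the array labelled EV control 2 wpi replicate 3 these counts became 119, 37 and 16, and the 16 were 6 higher and 10 lower and shared 2 probes with the 8. Leaving out single arrays moved them between 11 and 119, 1 and 37, and 0 and 4111. With same-numbered genotype pairs as a block the counts at 2 wpi were 22 with AMF and 17 in controls. Among probes that did not pass in controls, NIATv7_g03207.t1.cds1 had limma log2 differences of -6.14 at 2 wpi and -6.56 at 6 wpi (adjusted p = 0.087 and 0.052). In the same fit NIATv7_g34157.t1.cds1 had -4.79 and -5.84 (adjusted p = 0.17 and 0.15). A low number of calls in controls thus does not show that the lines differ little there.

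Averaged over the 4 conditions, 1576 probes differed between lines, 775 higher and 801 lower, of which 180 differed at least 2-fold, 115 higher and 65 lower. Normexp gave 552 higher and 830 lower, and quantile normalization 901 and 743. NIATv7_g03207.t1.cds1 fell by 6.88 ± 0.58 (SE) and NIATv7_g34157.t1.cds1 was lower, at -6.25 ± 0.72 in irCCaMK plants, on 4 of 12 arrays well above background, and -0.38 ± 2.34 in EV plants (SD, n = 12), while NIATv1_g52967.t1.cds1 was 3.36 ± 0.50 (SE) higher, with 9 of 12 EV arrays well above background, and NIATv1_g53765.t1.cds2 at least 2.83-fold higher. Of the 1576 probes, 1399 were also called with AMF at 6 wpi, and over the other 3 conditions alone 84 were called, 40 higher and 44 lower. The count was 874 without EV AMF 6 wpi replicate 1, 996 without irCCaMK AMF 2 wpi replicate 1, 2446 without EV control 2 wpi replicate 2 and 464 with brightness as a covariate.

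The series addresses how leaves respond to the fungus in the EV line and in the line silenced for CCaMK; root colonisation was not measured in these data. In EV plants the result depends on the processing. At 2 wpi limma gave 0 calls with 6775 probes at an unadjusted p below 0.05 and a smallest adjusted p of 0.052, and at 6 wpi 0 calls with 3934 probes and a smallest adjusted p of 0.054. The probes with the smallest p at 6 wpi included NIATv7_g01044.t1.cds2, at -0.16 ± 0.55 with AMF and -2.84 ± 0.43 in controls (SD, n = 3), NIATv7_g22097.t1.cds2, with a log2 difference of 3.22 ± 0.49 (SE) and 1 of 3 control arrays well above background, NIATv7_g01416.t1.cds1, with a difference of -3.42 ± 0.59, and NIATv7_g05642.t1.cds1, not well above background with AMF and at least 6.36-fold lower (adjusted p = 0.054). At 2 wpi they were NIATv7_g38981.t1.cds1, at -2.96 ± 0.12 with AMF and -4.49 ± 0.09 in controls, NIATv7_g38509.t1.cds1, with a log2 difference of 1.33 ± 0.21 (SE) and 1 of 3 arrays well above background in each group, NIATv7_g49555.t1.cds1 at -0.88 ± 0.14, and NIATv7_g08126.t1.cds1, which was not well above background with AMF and is given no fold; the other probe of its gene model measured 0.11. AMF and slide overlap in these contrasts. Without the slide term the counts were 177 at 2 wpi and 75 at 6 wpi, and within slide 2, over both lines and stages, 0 were called. At 2 wpi 5 probes were called under normexp and 4490 without EV control 2 wpi replicate 2. The latter fit leaves replicate 1 and the array whose label is in question as the EV controls at 2 wpi. At 6 wpi 88 were called without EV control 6 wpi replicate 1, 90 from the authors' table, 43 with trend and robust eBayes, 36 under normexp, 31 among probes well above background on all arrays, and 1 without the array labelled EV control 2 wpi replicate 3.

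In irCCaMK plants 332 probes differed with AMF at 2 wpi, 181 higher and 151 lower. NIATv7_g35076.t1.cds1, well above background on 2 of 3 AMF arrays, was at least 2.50-fold higher, NIATv7_g14737.t1.cds1 had a fitted log2 difference of 3.80 ± 0.84 (SE) with group means of -1.43 ± 3.47 and -3.54 ± 0.60 (SD, n = 3), NIATv7_g25163.t1.cds1 was at least 2.67-fold lower, and NIATv7_g24757.t1.cds1 was called lower but was not well above background in either group. At 6 wpi 1042 probes differed, 829 higher and 213 lower. NIATv7_g40584.t1.cds1 was higher by 8.45 ± 0.78 (SE), NIATv7_g39542.t1.cds1 was at least 88.4-fold higher, NIATv7_g02335.t1.cds1 fell by 3.81 ± 0.91, with 1 of 3 AMF arrays well above background, and NIATv7_g08085.t1.cds1 was at least 4.00-fold lower. Without the slide term the counts were 1303 and 2800, the latter 1490 higher and 1310 lower. With slide as a random block the calls at 6 wpi were 1355 higher and 1040 lower, so the size of the excess of higher calls depends on the slide term. With only the 2 groups compared, or within slide 2 over both lines and stages, both counts were 0. With array column in the model 299 probes were called at 2 wpi, 231 higher and 68 lower, and 98 of them were among the 332. At 2 wpi the count was 0 with the replicate number as a block and 678 without the array labelled EV control 2 wpi replicate 3. Over single arrays left out it ran from 0 to 1677. At 6 wpi it was 238 with the replicate number as a block, 381 without irCCaMK control 6 wpi replicate 3 and 391 without irCCaMK AMF 6 wpi replicate 1.

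**Figure D3:**
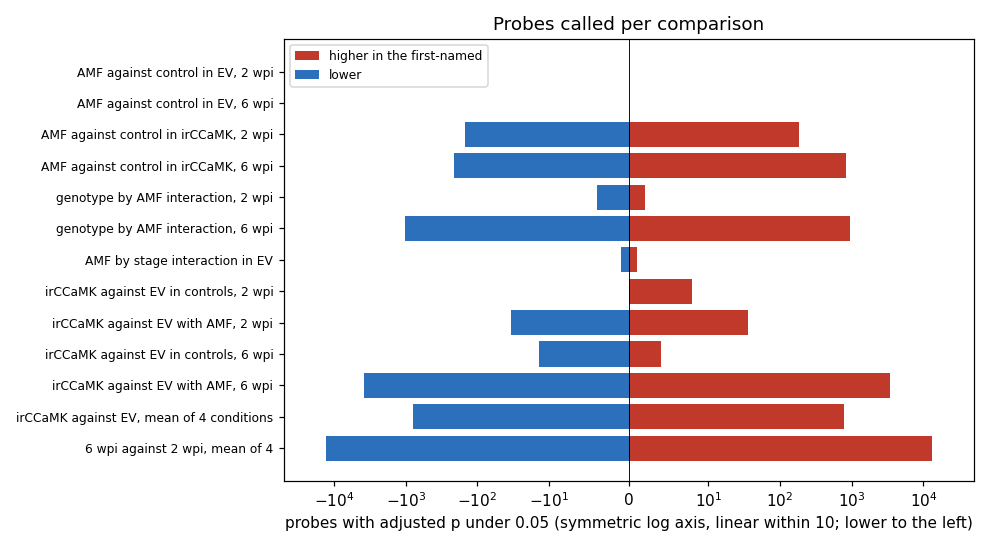
Number of probes with an adjusted p below 0.05 in each comparison, higher to the right in red and lower to the left in blue, on a symmetric log axis that is linear within 10. Stage has 26464 calls and irCCaMK against EV with AMF at 6 wpi 7220, and AMF against control in EV has 0 at both stages.

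The AMF effect itself differed between lines at 6 wpi. NIATv7_g04513.t1.cds2 had an interaction of -10.54 ± 1.11 (SE): in EV plants it measured -5.28 with AMF, on 1 of 3 arrays well above background, and -0.15 in controls, and in irCCaMK plants 3.61 with AMF and -1.80 in controls. NIATv7_g05642.t1.cds1 went the same way, at 2.76 with AMF and -3.66 in controls of the irCCaMK line and -2.52 in EV controls; it was not well above background in EV plants with AMF, so its interaction is given no size. NIATv7_g19069.t3.cds3 went the other way, with an interaction of 6.85 ± 1.27 and 1 of 3 arrays well above background both in EV controls and in irCCaMK plants with AMF; the 4 other probes of its gene model had interactions between -0.64 and -0.52. NIATv7_g04983.t1.cds1 was called in that direction too, without a size, since it was not well above background in EV controls or in irCCaMK plants with AMF. The limma fit called 1978 probes, 951 with a more positive effect in EV and 1027 with a more positive effect in irCCaMK. Normexp gave 1002 and 750, quantile normalization 789 and 1180, and the probes that differed at least 2-fold were 447 and 813. The count was 1197 without EV control 6 wpi replicate 3, 1103 without EV AMF 6 wpi replicate 1, 1048 without irCCaMK control 6 wpi replicate 3, 1308 without irCCaMK AMF 6 wpi replicate 3 and 1181 with brightness as a covariate. At 2 wpi 6 probes were called, 2 more positive in EV and 4 in irCCaMK (5 and 1 under normexp, 1 and 11 with quantile normalization, 8 and 7 from the authors' table). They include NIATv7_g06591.t1.cds1 at 4.53 ± 0.69, well above background on 1 of 3 arrays both in EV controls and in irCCaMK plants with AMF, and NIATv7_g08194.t1.cds1 at -2.74 ± 0.37. NIATv7_g11973.t1.cds2, more positive in EV, and NIATv7_g08126.t1.cds1, more positive in irCCaMK, were also called and are given no size. The former was not well above background in EV controls or in irCCaMK plants with AMF, and the latter only on 2 of the 12 arrays, with an interaction of 0.73, the opposite sign, at the other probe of its gene model. The count was 0 without the array labelled EV control 2 wpi replicate 3, 3369 without EV control 2 wpi replicate 2 and 970 without irCCaMK control 2 wpi replicate 1. It was 164 with array column in the model and 0 with same-numbered genotype pairs as a block. The AMF effect in EV plants differed between stages at 2 probes, NIATv7_g44830.t1.cds1 (1.75 ± 0.24), more positive at 6 wpi, and NIATv7_g39455.t1.cds1, more negative at 6 wpi and not well above background with AMF there. Without the array labelled EV control 2 wpi replicate 3 this count was 1, NIATv7_g39455.t1.cds1. Among probes that did not pass, NIATv7_g08912.t1.cds1 (1.78 ± 0.28) and NIATv7_g13774.t1.cds1 (-2.24 ± 0.34) had the smallest p of their direction, both with a limma adjusted p of 0.052. Calls more positive and more negative at 6 wpi were 1 and 2 under normexp, 2 and 1 with quantile normalization and 3 and 1 from the authors' table. Over single arrays left out the count ran from 0 to 2100, and with the replicate number as a block it was 11.

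Stage was the main axis of the data. NIATv7_g40011.t1.cds1 rose from -5.52 ± 0.98 at 2 wpi to 3.57 ± 0.92 at 6 wpi (SD, n = 12), and PRID1968077202 rose by 8.18 ± 0.33 (SE); at 2 wpi they were well above background on 4 and 6 of 12 arrays. NIATv7_g02841.t1.cds1 fell by 9.60 ± 0.43 and NIATv7_g19381.t1.cds1 fell by 9.59 ± 0.60, and at 6 wpi they were well above background on 1 and 8 of 12 arrays. The limma fit called 26464 probes, 79.5% of those tested, 13334 higher and 13130 lower at 6 wpi, and 8924 differed at least 2-fold, 3617 higher and 5307 lower. Within single slides 18445, 14639 and 20825 probes were called on slides 1, 2 and 3. Normexp correction gave 10114 higher and 16530 lower, with the median of all probes at -0.17 in place of 0.02.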

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

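The differences between groups below were planned, and all the tests of explanations but one were chosen after the result was seen; the exception is the position at probes called in the 6 wpi controls.

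A test of the difference itself set 3 results apart: the AMF effect differed between lines at 6 probes at 2 wpi and at 1978 probes at 6 wpi, and between stages in EV plants at 2 probes. Of 100 splits of the arrays, the real one included, 6 gave as many calls as the interaction at 2 wpi (highest other 313) and 17 as many as the AMF by stage interaction (highest other 18604), so chance cannot be excluded for these; the latter splits are drawn across both stages, and such a count points to the stage structure of the arrays. For the interaction at 6 wpi 4 of 100 did, a share below 0.05, with a highest other count of 3660. These splits exchange arrays freely over all groups at 6 wpi. They ask whether the groups differ in any way, not whether the interaction alone is absent, so chance is not excluded for the interaction. Splits that call more than the real one point to a structure of the arrays. For the mean genotype and stage comparisons 1 of 100 splits, the real one, reached 1576 and 26464 calls (highest others 743 and 17631). This share, below 0.05, argues against chance alone. These splits exchange arrays within each condition for the lines, and within each genotype-treatment combination for stage. A difference in 1 of these is enough for such a result, so it does not show a difference common to all.

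With 3 arrays against 3 there are 10 splits, too few for a share below 0.05. For irCCaMK against EV with AMF at 6 wpi the real count was 7220 and the highest other 0, with AMF at 2 wpi 70 and 1, and in controls at 6 wpi 18 and 0. For AMF in irCCaMK plants they were 332 and 2 at 2 wpi, and 1042 and 2 at 6 wpi. In 1 of 10 splits, the real one, these counts were reached. For the lines in controls and for AMF in irCCaMK plants, both at 6 wpi, the other splits that part every same-numbered pair gave 0; the split with 2 calls parted 1 pair and kept 2 together. For AMF in EV plants at 6 wpi the real count was 0 and the highest other 6, with all 10 splits giving as many. For AMF in EV plants at 2 wpi (0 calls, all 10 splits) and for the lines in controls at 2 wpi (8 calls, 3 of 10 splits), the highest others were 3355 and 931, both in splits that put EV control 2 wpi replicates 1 and 3 together against replicate 2, which points to a structure of those arrays.

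The array labelled EV control 2 wpi replicate 3 lies on the irCCaMK side at genotype-marker probes, beyond the irCCaMK controls of its own stage. On a score of 289 probes chosen from the other 3 conditions, 0 being the EV and 100 the irCCaMK level with AMF at 2 wpi, it reached 111, above the 35.8 to 49.5 of the irCCaMK controls at 2 wpi; scored in the same way from their own other conditions, the other EV arrays of the series lay between -25.1 and 19.7 and the irCCaMK arrays between 35.8 and 114. An exchange with an irCCaMK array is argued against by the lowest irCCaMK score, 35.8, above every other EV array, and a mixture by NIATv7_g03207.t1.cds1, at 0.303% of the EV level with AMF. The array also lies toward irCCaMK AMF 6 wpi on component 2. At the 7 usable probes of the 18 called in the 6 wpi controls its median position was 137, on a scale from the other 2 EV arrays (0) to irCCaMK (100). These 2, scored only against each other, had -11.2 and 11.5, which shows their spread and is no independent level. Probes called in those controls can also differ between lines with AMF at 6 wpi, as NIATv7_g39755.t1.cds1 did (log2 differences of -2.87 and -2.86). A shift along that axis in an EV plant would move such probes too, so this position cannot argue against it. A wrong label, a plant of the other line or such a shift may account for the array's values, and each stays open.

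Plants of the irCCaMK line with AMF at 6 wpi stand apart, and their arrays are brighter. Of the probes called on slide 3 alone, 95.0% moved the same way on slide 2, which argues against 1 slide or 1 array. With brightness in the model 3182 of the 7220 calls (44.1%) remained, below the share of 0.5 set first as the bound for brightness, but a larger error lowers this count too and the median SE rose from 0.189 to 0.236. A test of size was then added: the median log2 difference of the 7220 calls went from 0.82 to 0.75. A linear brightness slope, estimated within groups, thus accounted for little of the median size. These calls were chosen in the fit without brightness, and the covariate moves with the group. The test of size therefore cannot decide whether brightness is the source. The median of the calls kept went from 1.036 to 1.065, but these were chosen for passing with brightness in the model, so this adds no support. For the calls lost the median went from 0.69 to 0.564, so they ended through a smaller fold and a larger error. Brightness and group cannot be told apart for the calls lost or kept, and a biological difference with AMF is open too.

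AMF calls appear when the slide term is left out. Between slides 2 and 3, 686 probes differed within AMF groups and between slides 1 and 2 within controls 0, so a slide difference could account for part of these calls. Of the calls made without the term, 55.9% and 46.7% in EV and 65.2% and 65.4% in irCCaMK plants, at 2 and 6 wpi, went the way of slide 3 against slide 1, and on slide 2, which holds both treatments, 100%, 100%, 99.9% and 99.3% had the same sign; the arrays of slide 2 are among those that made these calls. An effect of AMF on the leaf is not excluded.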

How the results depend on the processing

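Alternatives with brightness, with slide 1 or 3 alone, and without the array labelled EV control 2 wpi replicate 3 and the slide term were chosen after the data were examined. Counts of calls follow the order EV then irCCaMK for AMF, controls then AMF for the lines, 2 wpi before 6 wpi; counts not given stayed within 1.5 times, and causes were not tested unless stated.

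Without the slide term AMF gave 177 and 75 calls in EV and 1303 and 2800 in irCCaMK plants, AMF by stage 6, and the lines in controls at 2 wpi 0. With slide as a random block these were 50, 63, 1043, 2395, 6 and 3. With array column added, the interaction at 2 wpi gave 164, AMF by stage 6, and the lines 4 in controls at 2 wpi, 113 with AMF at 2 wpi and 5 in controls at 6 wpi. Normexp gave 5 and 36 for AMF in EV, and 0 and 35 for the lines at 2 wpi. Quantile normalization gave 3 for AMF in EV at 2 wpi, 12 for the interaction at 2 wpi, and 4 and 116 for the lines at 2 wpi, and median scaling 1 for AMF in EV at 2 wpi. Without a filter on dim probes, which tests more probes, AMF in irCCaMK gave 5 and 649, the interactions 0 and 1038, AMF by stage 0, the lines 0, 23 and 1 (controls and AMF at 2 wpi, controls at 6 wpi), their mean 720, and stage 43357. With only the probes well above background on all arrays, AMF gave 31 in EV at 6 wpi and 542 in irCCaMK at 2 wpi, the interaction at 2 wpi 1, AMF by stage 4, and the lines in controls at 2 wpi 0. The authors' table gave 90, 767, 15, 4 and 0 for the same results and 174 for the lines with AMF at 2 wpi. Trend and robust eBayes gave 43, 525, 6 and 0 (AMF in EV at 6 wpi, in irCCaMK at 2 wpi, AMF by stage, lines in controls at 2 wpi).

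With only the groups compared, which leaves fewer arrays, AMF in irCCaMK gave 0 at both stages, the interaction at 2 wpi 0, AMF by stage 0, and the lines 0, 17, 7 and 4069. A 2-fold minimum gave 192 for AMF in irCCaMK at 2 wpi, 1260 for the interaction at 6 wpi, 2760 for the lines with AMF at 6 wpi, 180 for their mean and 8924 for stage. Within slide 2 AMF gave 0 calls and stage 14639. Slide 1 alone gave 2 and 3 for the lines in controls, and slide 3 alone 16 and 2359 with AMF. Brightness as a covariate gave 1 for AMF in EV at 6 wpi, 211 in irCCaMK at 2 wpi, interactions of 0 and 1181, AMF by stage 1, the lines 0, 29, 2 and 3588, and their mean 464. Without the array labelled EV control 2 wpi replicate 3 and the slide term, AMF gave 15, 80, 1830 and 3316, the interaction at 2 wpi 0, AMF by stage 1, and the lines in controls 19 and 37.

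Arrays with the same replicate number paired in 2 comparisons, the lines in controls at 6 wpi and AMF in irCCaMK plants at 6 wpi, where all pairs had a correlation of deviations over 0.1; after the slide term the lowest were 0.002 and 0.066. In the other 6 comparisons not every pair was over this bound, which does not show that the pairs are unrelated. Same-numbered EV and irCCaMK arrays of one treatment and stage always lay next to each other on the same slide. Same-numbered control and AMF arrays of one line and stage never shared a slide. Over all, 7 of 12 EV and irCCaMK pairs were over 0.1 (-0.242 to 0.658), and 6 of 12 control and AMF pairs. In no comparison did every array correlate best with its own number. With the replicate number as a block, AMF in irCCaMK gave 0 and 238 and AMF by stage 11, and with same-numbered genotype pairs as the replicate block the interaction at 2 wpi gave 0 and the lines 17, 22 and 6 (controls and AMF at 2 wpi, controls at 6 wpi). The block moved no other count by over 1.5 times.

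Leaving out 1 array at a time, where a group of 2 is assumed to vary like the others, AMF in EV gave 0 to 4490 calls at 2 wpi and 0 to 88 at 6 wpi, and in irCCaMK 0 to 1677 and 381 to 1302. The interactions gave 0 to 3369 and 1048 to 2286, AMF by stage 0 to 2100, the lines in controls 0 to 4111 and 1 to 37, with AMF 11 to 119 and 4228 to 8029, their mean 874 to 2446, and stage 25914 to 26854. The highest counts of AMF in EV at 2 wpi, the interaction at 2 wpi, AMF by stage and the lines in controls at 2 wpi came without EV control 2 wpi replicate 2. That fit leaves replicate 1 and the array labelled replicate 3, whose label is in question, as the EV controls at 2 wpi. Of named probes, NIATv7_g08126.t1.cds1 turned to 0.12 in the interaction at 2 wpi under normexp, and NIATv7_g05642.t1.cds1 and NIATv7_g01416.t1.cds1, negative for AMF in EV at 6 wpi, had values of 1.08 and 0.37 within slide 2; these are mean AMF effects over both lines and stages, not estimates for EV at 6 wpi. Outside the left-out arrays 507 named-probe values kept their direction and side, 142 were weaker and 44 stronger. Values of probes near background are limited by signal over background.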

Other observations

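The tests here were chosen after the result was seen. Of the 7220 probes that differed between lines with AMF at 6 wpi, 5615 were also called between stages in the control plants. Of all 33280 tested probes 23912 were called between stages there, so any set of probes would overlap widely. Of the 5615 probes called in both, 3973 (70.8%) differed opposite to the stage change, where independent directions would give 50%. Among those higher in irCCaMK plants 2407 of 2814 (85.5%) were lower at 6 wpi in controls, and among those lower 1566 of 2801 (55.9%) were higher at 6 wpi. The 50% does not allow for probes tested because they were bright at 2 wpi and at background at 6 wpi. Such probes could differ only upward, which is opposite to stage. NIATv7_g39542.t1.cds1, well above background on every array at 2 wpi, was so on 0 of 3 in EV plants with AMF at 6 wpi. The excess over 50% is therefore no measure of a link with stage. Of the 574 probes called at least 4-fold higher in irCCaMK plants, 470 were called lower at 6 wpi in controls, and 466 of these were at least 2-fold lower at 6 wpi in EV plants with AMF. At these 466 the irCCaMK plants with AMF lay a median of 74.1% of the way from the EV level at 6 wpi back to that at 2 wpi (quartiles 60.8 and 91.9%). The EV and irCCaMK levels with AMF at 6 wpi enter both the choice of these probes and the position, so the choice favoured a large share.

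A hypothesis, drawn from the 70.8% of probes opposite to stage and so not tested by it, is that leaves of irCCaMK plants with AMF at 6 wpi kept part of a rosette-stage programme. No value here decides it. A uniform lag as the whole difference is argued against, since 5242 of the 7220 calls remained with each array's stage score as a covariate. The mean score of irCCaMK plants with AMF at 6 wpi was 81.2 ± 14.5 (SD, n = 3). The scale runs from 0, the mean of the controls of both lines at 2 wpi, to 100, their mean at 6 wpi. A control array was left out of its own reference. Beside the 81.2 stood 98.4 ± 11.5 in irCCaMK controls, 99 ± 15.8 in EV controls (replicate 1 at 80.8) and 100 ± 6.13 in EV plants with AMF, all at 6 wpi. The control means lie near 100 by construction, so only EV plants with AMF give an outside level. Replicates 1 to 3 with AMF scored 65.0, 92.9 and 85.7, each below the irCCaMK control of the same number (85.6, 107.8 and 101.9). These same-numbered arrays lay on different slides, and control replicate 1 scored below AMF replicates 2 and 3. The differences in score were not tested. Brightness, which differs for the same 3 arrays, cannot be told apart from the group and stays open as a source.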
